A study of Sus scrofa with 105 samples.

How the data were processed

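Small RNA libraries had been made from fixed, paraffin-embedded brain of female piglets (Sus scrofa) in a study of pediatric diffuse traumatic brain injury. The tissue was the frontal lobe or the hippocampus together with the amygdala. Per the labels' protocols, total RNA was extracted with a Mag-Bind kit for such fixed tissue, and libraries were prepared from total RNA with the QIAseq miRNA kit. The series holds 105 libraries of 53 animals, told apart by the animal code in each library's name, and 52 of the animals gave both regions. Per the series design text 50 subjects passed library preparation, so the number of animals is uncertain, as is whether each code stands for 1 animal. If it does, each region has 1 library per animal and replicates are animals, as is assumed throughout. The 4 groups are sham or naive animals (survival 0 to 8 days), injured animals at 1 day, injured animals at 1 week (6 to 8 days), and injured animals given cyclosporine A (CsA, a calcineurin inhibitor and immunosuppressant) that survived 30 hours. Per the labels, CsA was given intravenously at 20 mg/kg per day, with a loading dose 6 hours after injury followed by an infusion of 24 hours.

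The deposited table holds whole-number counts per porcine mature miRNA and library, not normalized. Per the submitters' processing notes, Trimmomatic 0.39 and cutadapt 1.9.1 were used. The aligner, the counting tool, the miRNA annotation, the genome build and the use of molecular identifiers are not given in the sources used here. The counts are therefore treated as reads that need not be independent molecules. The table has 542 entries, of which 89 were 0 in every library. Many entries carry the same mature name once per precursor, and 457 mature names remain. Entries of the same mature name, and entries of different names with a total of at least 100 whose counts differed by less than 0.01 of the larger total, were taken to hold the same reads and were merged to the entry with the highest total. This removed 94 entries and left 448 miRNAs. The rule was chosen after the structure of the table was seen and before any test; the deposited entries without merging were run as an alternative. The 6 merged sets of different names are miR-9 with miR-9-1 and miR-9-2, miR-129a-5p with miR-129b, miR-199a-3p with miR-199b-3p, miR-218 with miR-218-5p and miR-218b, miR-339 with miR-339-5p and miR-4334-3p, and miR-490 with miR-490-3p. Members of a family that differ by few bases, let-7 in particular, may share reads, so their single values are uncertain. All columns of the table were mapped to samples by name, and the most similar pair of libraries still differed beyond sampling noise (chi-square 17080 on 294 degrees of freedom), so none was counted as a repeat. No miRNA sequences or coordinates were used here.

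Differential abundance was tested on the counts with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust estimation) in R 4.3.3, after TMM scaling and filterByExpr at its defaults (minimum count 10, minimum total 15), with Benjamini-Hochberg adjustment within each comparison at 0.05. All tests were 2-sided. Within a region all 4 groups entered 1 fit, which shares the dispersion, and 5 differences were tested: 1 day minus sham, 1 week minus sham, CsA minus 1 day, CsA minus sham and 1 week minus 1 day. The regions were compared in a separate fit of the 52 animals with both, with the animal as a block, because the same code marks the same animal. The correlation of the deviations of both libraries of an animal from their group means had a median of 0.253 over these pairs (0.1 was exceeded in 39) against -0.00614 for libraries of different animals. That fit gave the region difference within sham animals and whether each injured group differed from sham by another amount in 1 region (interaction). Abundance is given as CPM with TMM factors (a count scaled by its library total), mean ± SD over animals, and log2 fold changes are edgeR's, with their standard error (SE). Fold values are their antilogs.

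Groups, alternatives, designs, 21 lists of miRNAs and the rule for naming miRNAs were fixed before the data were examined. The rule takes, per comparison, miRNAs past the threshold with at least 10 CPM on average in either group, the 12 with the largest increase and the 12 with the largest decrease. Where fewer than 3 pass, it takes the 5 with the smallest p. A panel is added in every comparison: miR-21, miR-155, miR-146a, miR-146b, miR-223, miR-142, miR-124, miR-9, miR-132, miR-212, miR-219, miR-338, miR-451, miR-486, miR-126 and miR-210. Lists are described by members with the smallest p or the highest mean. The lists are neuron-enriched, activity-regulated neuronal, oligodendrocyte and myelin, astrocyte-associated, microglia and inflammation, blood leukocyte, erythrocyte, endothelial and vascular smooth muscle, skeletal muscle, epithelial and choroid plexus, liver and gut, hypoxia, p53 and cell death, mitochondria-associated, reported in traumatic brain injury, the imprinted DLK1-DIO3 cluster, the let-7, miR-17-92, miR-30 and miR-181 families, and caudal HOX-cluster miRNAs. Each list was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 252 tests of lists with at least 3 measured members. The liver and gut, hypoxia and caudal HOX-cluster lists had fewer and were only counted. Camera compares a list with the other miRNAs, and fry asks whether its members move, on balance, 1 way.

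Library totals were compared on the log10 scale by permutation tests with 100000 resamples, exact where a group had fewer than 10 animals. Alternatives were RLE factors, no low-count filter, DESeq2 1.42.0, limma voom with quality weights, no shallow libraries (under 0.5 of the region's median total), only the 2 groups compared, the letter or the first 2 digits of the animal code as a covariate, and only animals with a given letter or given first digits. Those chosen after seeing the data were the entries as deposited, log10 total as a covariate, no let-7 family and thinning to equal totals without the shallow libraries. Others chosen then were only codes beginning 12 or 13 or beginning 11, and leaving out each library of the groups compared in turn (each animal where both regions enter). Comparisons that share libraries were set beside 1000 shuffles with no effect and beside values with the shared libraries divided into 2 parts. Chance was gauged with 100 splits of the animals, the real one included, or 40 for the fit with the animal as a block. The procedure was tested on simulated data drawn from the real means, dispersions and totals, with no difference between code groups. Each miRNA was drawn independently, so simulated abundances did not follow the library total and miRNAs did not vary together between animals. False calls and recovery may therefore differ in the real data. From 0 to 6 unchanged miRNAs were called per comparison. Of 20 miRNAs changed 2-fold, 95% and 100% were recovered for 1 day minus sham (frontal, then hippocampus with amygdala), 80% and 95% for 1 week minus sham, 85% and 85% for CsA minus 1 day, 80% and 90% for CsA minus sham, 95% and 90% for 1 week minus 1 day, and 95% for the region difference. At 1.5-fold, of 19 or 20 miRNAs, 55% and 75% were recovered for 1 day minus sham, 50% and 85% for 1 week minus sham and 45% and 63.2% for CsA minus 1 day. For CsA minus sham the shares were 70% and 75%, for 1 week minus 1 day 90% and 63.2%, and for the region difference 75%. The interactions were less well covered, with 85% of 20 for 1 day, 73.7% of 19 for 1 week and 65.0% of 20 for CsA at 2-fold, and 50.0%, 45.0% and 25.0% at 1.5-fold. Figures and permutation tests used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.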

Results

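Small RNA was sequenced from 105 fixed, paraffin-embedded brain samples of 53 female piglets, as a count per mature miRNA and library. The frontal lobe gave 52 libraries: 18 from sham or naive animals, 10 from animals 1 day after diffuse traumatic brain injury, 15 at 1 week, and 9 from injured animals treated with cyclosporine A (CsA) and studied at 30 hours. The hippocampus together with the amygdala gave 53 libraries, 18, 10, 15 and 10 in the same order. Library totals after merging repeated entries ran from 98008 to 12703535 counts, with a median of 7257404. After filtering, 284 miRNAs were tested in the frontal lobe and 290 in the hippocampus and amygdala. The let-7 family took most of the counts, 79.6% ± 3.18 (SD, n = 18) in frontal sham libraries and 75.0% ± 1.40 (n = 10) at 1 day. Its share in the hippocampus and amygdala was 78.4% ± 3.31 and 72.7% ± 1.99.

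Totals differed between the groups. At 1 day the geometric mean total was 2.44 times that of sham in the frontal lobe (permutation p = 0.00146, adjusted p = 0.00389 over 8 tests) and 2.09 times in the hippocampus and amygdala (p = 0.00048, adjusted p = 0.00192). The CsA groups had 2.16 times (exact permutation p = 0.00944, adjusted p = 0.0189) and 2.10 times (permutation p = 0.00028, adjusted p = 0.00192) the sham totals. At 1 week the ratios were 1.67 and 1.47 and did not pass (permutation, adjusted p = 0.168 for both). CsA against 1 day gave 0.883 (exact permutation, adjusted p = 0.281) and 1.01 (permutation, adjusted p = 0.904). The animal codes in the library names were unevenly spread as well. All 1 day and CsA animals had the letter U and codes beginning 11, 12 or 13. The sham group held 6 animals with the letter U, 5 with none, 2 with B, 2 with F and 3 with I. In it, 11 of 18 codes began with 11, 12 or 13. No sham or 1 week animal shared both the letter and the first 2 digits with a 1 day or CsA animal. Some sham and 1 week animals shared the whole code before the hyphen, as did some 1 day and CsA animals, and no test took this into account. What the codes stand for is not given in the sources used here. Among codes beginning 12 or 13, 1 day and sham totals were alike in the frontal lobe (ratio 1.20, exact permutation p = 0.46, n = 5 and 5). Among codes beginning 11 the ratio was 3.41 (exact permutation p = 0.00433, n = 5 and 6).

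**Figure D1:**
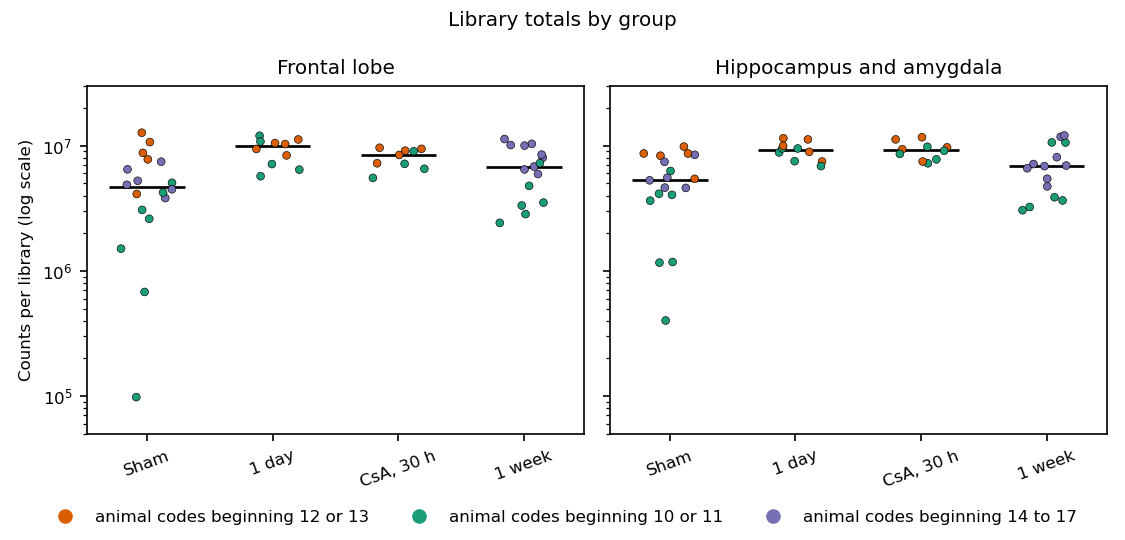
Total counts per library on a log scale by group, in the frontal lobe (left) and in the hippocampus and amygdala (right); each point is 1 library, coloured by the first 2 digits of its animal code, and black lines are medians. Frontal medians are 4679652 counts in sham and 9866050 at 1 day, and the lowest library, a frontal sham, holds 98008.

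Injury at 1 day was first set against sham in the frontal lobe, the question being which miRNAs change soon after diffuse injury. miR-212, transcribed from an activity-responsive neuronal locus, was 1.94-fold higher at 1 day (16.1 ± 2.20 CPM, n = 10, against 7.79 ± 3.98, n = 18; log2 0.95, SE 0.23, adjusted p = 0.000873), while miR-132 from the same transcript was not (log2 -0.07, adjusted p = 0.595). miR-9, a miRNA of neural progenitors and neurons, rose 1.51-fold from 9129 ± 4105 to 13810 ± 2975 CPM (adjusted p = 0.00322), and miR-107 rose by log2 0.59 (adjusted p = 0.000181); 100% of the 1 day animals lay above the sham median for each. miR-124a, the most abundant neuron-specific miRNA in mammals, fell by 0.47 on the log2 scale (10110 ± 1690 to 7303 ± 1270 CPM, SE 0.11, adjusted p = 0.000356). Larger decreases were seen for miR-139-3p, 3.55-fold lower (174.9 ± 55.7 against 623.4 ± 294.3 CPM, adjusted p = 3.21e-05), miR-423-5p, 3.92-fold lower (adjusted p = 3.21e-05), and miR-885-3p, 4.07-fold lower.

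In all, 127 of the 284 miRNAs tested differed, 53 higher and 74 lower. The split depended on the scaling: RLE factors gave 74 higher and 63 lower, DESeq2 76 and 68, and leaving out let-7 73 and 62. The 12 named decreases began at 3.06-fold for miR-296-3p, and the size of the largest rested on single sham animals with high values, though each passed without them. miR-10386, a porcine miRNA, was 46.1-fold lower (42.9 ± 26.0 against 2005 ± 4161 CPM) and 29.9-fold lower without sham replicate 16. Without sham replicate 15, the library with the lowest total, the decrease went from 17.6-fold to 8.94-fold for miR-4332, from 9.60-fold to 3.87-fold for miR-4331-3p and from 7.60-fold to 2.09-fold for miR-574-5p (adjusted p = 0.00546). miR-92b-5p (5.18-fold), miR-193a-5p (3.95-fold), miR-769-3p (3.20-fold) and miR-1307 (3.12-fold) were also lower. Increases were smaller, with miR-148b-3p at 1.77-fold, miR-27a at 1.70-fold, miR-505 at 1.66-fold, miR-17-3p at 1.60-fold, miR-22-5p at 1.60-fold, miR-363 at 1.59-fold, miR-574-3p at 1.59-fold, miR-30c-5p at 1.52-fold and miR-885-5p at 1.51-fold. Of the panel, endothelial miR-126-3p rose (log2 0.28, adjusted p = 0.0273), and miR-219b-3p (log2 -0.29), miR-338 (log2 -0.30) and miR-486 (log2 -0.85) fell. The miR-126-3p call was lost without sham replicate 8 or without 1 day replicate 8 or 9 (adjusted p up to 0.0575), and that of miR-338 without any of 13 of the 28 animals (up to 0.111). miR-21-5p (log2 0.32, adjusted p = 0.0557), miR-155-5p (0.08), miR-146a-5p (0.08), miR-146b (0.30), miR-223 (0.14), miR-142-5p (0.17), miR-142-3p (-0.47, adjusted p = 0.0654), miR-126-5p (0.23, adjusted p = 0.159), miR-21-3p (0.15), miR-219a (0.01), miR-210 (0.09) and erythroid miR-451 (log2 1.22, adjusted p = 0.0546) did not pass. With 1 animal left out, miR-21-5p passed in 14 of 28 cases (adjusted p from 0.0164), miR-451 in 6 (from 0.00537, without sham replicate 7), miR-142-3p without sham replicate 3 or 17 (0.0390 and 0.0424), miR-126-5p without sham replicate 9 (0.0295) and miR-146b without sham replicate 5 (0.0438).

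Among the lists, p53 and cell death miRNAs had 4 of 9 measured members higher and 0 lower (4 and 0 adjusted over the list alone): miR-107, miR-15b (log2 0.58), miR-103 (0.33) and miR-16 (0.23). Astrocyte-associated miRNAs had 5 of 9 higher and 0 lower (5 and 0 over the list alone), among them miR-29a-3p (log2 0.38) and miR-27b-3p (0.57). Of miRNAs reported in traumatic brain injury, 8 of 22 rose and 2 fell (10 and 2 over the list alone), with miR-130a (log2 0.54) and miR-9 up and miR-184 (-0.95) and miR-124a down. Camera called none of these (adjusted p = 0.150, 0.150 and 0.0821), whereas fry gave adjusted p = 0.00282, 0.0262 and 0.00205, higher, and 0.0359 for erythrocyte miRNAs, also higher. Neuron-enriched miRNAs split 4 higher and 2 lower of 11 (same over the list alone), activity-regulated ones 2 and 1 of 4, oligodendrocyte and myelin ones 0 and 2 of 3, and the DLK1-DIO3 cluster 1 and 3 of 18, with miR-370 at log2 -1.05. The let-7 family had 1 higher and 3 lower of 10, with let-7e (-0.87) and let-7c (-0.77) among the lower ones. The miR-30 family had 4 and 3 of 10 (4 and 4 over the list alone), the miR-17-92 group 4 and 1 of 11, and the miR-181 family 2 and 0 of 5 (1 and 0 over the list alone). Microglia and inflammation miRNAs (0 of 8) and blood leukocyte miRNAs (0 of 5) held no call by edgeR, over all miRNAs or over the list alone. Erythrocyte miRNAs gave 2 and 1 of 4 (3 and 1 over the list alone), skeletal muscle 0 and 1 of 4 (1 and 1), and mitochondria-associated 3 and 2 of 13 (2 and 1). Endothelial and vascular smooth muscle miRNAs gave 3 and 0 of 11, epithelial and choroid plexus 1 and 0 of 6, and caudal HOX-cluster 0 and 1 of 2 (miR-10a-5p, log2 -1.41). The single measured members of the liver and gut list and of the hypoxia list did not pass. Median and mean differed in sign for the endothelial list (log2 -0.11 and 0.04), the DLK1-DIO3 cluster (0.09 and -0.01), the miR-30 family (0.06 and -0.01) and the miR-181 family (-0.17 and 0.02), and camera placed the leukocyte list up though both were below 0 (-0.03 and -0.05).

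The frontal difference was not the same in every code group. With codes beginning 11, 5 animals at 1 day against 6 sham gave 91 calls, 42 higher and 49 lower, of which 83 were among the 127; without 1 day replicate 2 the count was 55. With codes beginning 12 or 13, 5 against 5 gave 0 calls by edgeR, with 61 at an unadjusted p under 0.05. Of 125 of the 127 also tested there, 122 kept their sign, at a median of 0.606 of the full difference. These libraries are part of the full comparison, and the miRNAs were chosen for being called in it. Agreement in sign is therefore partly built in. Log10 total as a covariate left 56 calls (8 higher, 48 lower). Within the 18 frontal sham animals, miRNAs named above differed in how far they followed the library total. For miR-10386 Pearson r with log10 total was -0.861 (permutation p = 2e-05, the smallest possible, adjusted p = 4.9e-05 over 32 relations) and Spearman rho -0.913 (p = 2e-05, adjusted p = 0.00016), with r = -0.85 without the 2 farthest totals. miR-4332, miR-4331-3p and miR-574-5p had r of -0.897, -0.95 and -0.925 (adjusted permutation p = 4.9e-05 each) and rho of -0.881, -0.759 and -0.734 (adjusted p = 0.00016, 0.00089 and 0.0017), with r of -0.796, -0.766 and -0.68 without 2 animals. The ranks of miR-139-3p and miR-423-5p did not pass: r was -0.474 (permutation p = 0.0096, adjusted p = 0.011) and -0.545 (p = 0.0039, adjusted p = 0.0051), but rho -0.288 (p = 0.25, adjusted p = 0.25) and -0.335 (p = 0.17, adjusted p = 0.18), with r of -0.432 and -0.433 without 2 animals. For miR-9 r was 0.644 (permutation p = 0.0001, adjusted p = 0.0002) and rho 0.649 (p = 0.0045, adjusted p = 0.0066), with 0.649 without those 2.

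In the hippocampus and amygdala, 1 day minus sham showed many of the same miRNAs. miR-9 was 1.67-fold higher (14700 ± 2918 CPM, n = 10, against 8815 ± 2804, n = 18; log2 0.74, SE 0.14, adjusted p = 0.000104) and miR-212 1.92-fold higher (adjusted p = 0.00219). miR-21-5p, a miRNA induced in reactive glia and immune cells, rose 1.35-fold from 104.3 ± 19.7 to 140.7 ± 35.9 CPM (adjusted p = 0.00442). miR-142-5p (1.41-fold, adjusted p = 0.00789) and miR-223 (1.41-fold, adjusted p = 0.0295), both of blood-derived immune cells, and miR-155-5p (1.14-fold, adjusted p = 0.0492) rose too. The miR-223 call was lost without 1 day replicate 2, 3, 5 or 7 (adjusted p up to 0.102) and that of miR-155-5p without any of 21 of the 28 animals (up to 0.169). The other arm, miR-142-3p, was at log2 -0.45 (adjusted p = 0.0597) and did not pass, except without any of 8 animals (from 0.0171). Erythroid miR-451 rose by log2 1.85 from 1.40 ± 1.60 to 5.16 ± 4.10 CPM (adjusted p = 0.00310). miR-139-3p was 2.36-fold lower (411.6 ± 112.8 against 972.2 ± 363.1 CPM, adjusted p = 9.02e-05) and miR-423-5p 2.48-fold lower.

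The test called 141 of 290, 82 higher and 59 lower; RLE factors gave 69 and 70, DESeq2 72 and 72, and leaving out let-7 64 and 67. Named increases ran from 1.60-fold for miR-664-3p to miR-212, and included miR-363 (1.75-fold), miR-374a-5p (1.73-fold), miR-27a (1.71-fold), miR-17-3p (1.68-fold), miR-221-5p (1.64-fold), miR-30c-5p (1.63-fold), miR-31 (1.62-fold), miR-15b (1.62-fold) and miR-505 (1.61-fold). Named decreases ran from 2.25-fold for miR-296-3p to 27.4-fold for miR-10386 (47.8 ± 24.2 against 1313 ± 2084 CPM), with miR-4332 at 9.54-fold (6.98-fold without sham replicate 6), miR-4331-3p at 4.52-fold (3.05-fold without it), miR-574-5p at 3.11-fold (2.11-fold without it), miR-885-3p at 3.36-fold, miR-92b-5p at 3.13-fold, miR-193a-5p at 3.07-fold, miR-769-3p at 2.98-fold and miR-1307 at 2.27-fold. Also in the panel, miR-126-3p (log2 0.41) and miR-126-5p (0.28) rose and miR-124a (-0.33, adjusted p = 0.0150) fell, while miR-132 (-0.05), miR-146a-5p (-0.60), miR-146b (0.62), miR-338 (-0.25), miR-219b-3p (-0.21), miR-486 (-0.40), miR-219a (-0.42), miR-21-3p (0.10) and miR-210 (0.12) did not pass. The miR-126-5p call was lost without sham replicate 7 or 15 or 1 day replicate 2, 3 or 8 (adjusted p up to 0.132). With 1 animal left out, miR-486 passed in 4 cases (from 0.0265), miR-146b without sham replicate 13 (0.0321), miR-338 without 1 day replicate 2 (0.0470) and miR-219b-3p without sham replicate 2 (0.0494).

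By list, miRNAs reported in traumatic brain injury had 14 of 23 higher and 2 lower (15 and 2 adjusted over the list alone), with miR-107 (log2 0.56), miR-23b (0.62) and miR-16 (0.39) among the higher ones. Astrocyte-associated miRNAs had 6 of 9 higher and 0 lower (7 and 0 over the list alone), and p53 and cell death miRNAs 4 of 9 and 0. Microglia and inflammation miRNAs had 4 of 8 higher and 0 lower (4 and 1 over the list alone), blood leukocyte 2 of 5 and erythrocyte 3 of 5 (3 and 1 over the list alone). Adjusted camera p was 0.0821 for the traumatic brain injury list, 0.150 for the astrocyte list and 0.167 for the p53 list, with fry at 7.10e-06, 0.00282 and 0.00680. Fry also gave 0.00282 for erythrocyte and 0.0306 for endothelial and vascular smooth muscle miRNAs, both higher. Counts elsewhere were 5 higher and 2 lower of 11 neuron-enriched miRNAs (6 and 2 over the list alone), 4 and 3 of 19 in the DLK1-DIO3 cluster, 3 and 2 of 10 in the let-7 family (median log2 0.13, mean -0.04), 4 and 3 of 10 in the miR-30 family, 4 and 1 of 11 in the miR-17-92 group, 2 and 0 of 5 in the miR-181 family, 3 and 0 of 11 endothelial and vascular smooth muscle miRNAs (2 over the list alone) and 3 and 0 of 13 mitochondria-associated ones. With codes beginning 11 the comparison gave 112 calls (56 higher, 56 lower; 100 of them among the 141), and with codes beginning 12 or 13 it gave 0 by edgeR, with 53 at an unadjusted p under 0.05 and 128 of 140 keeping their sign, at a median of 0.432 of the full difference. The libraries with codes 12 or 13 are part of the full comparison here too, so agreement in sign is partly built in. With log10 total as a covariate 57 were called.

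**Figure D2:**
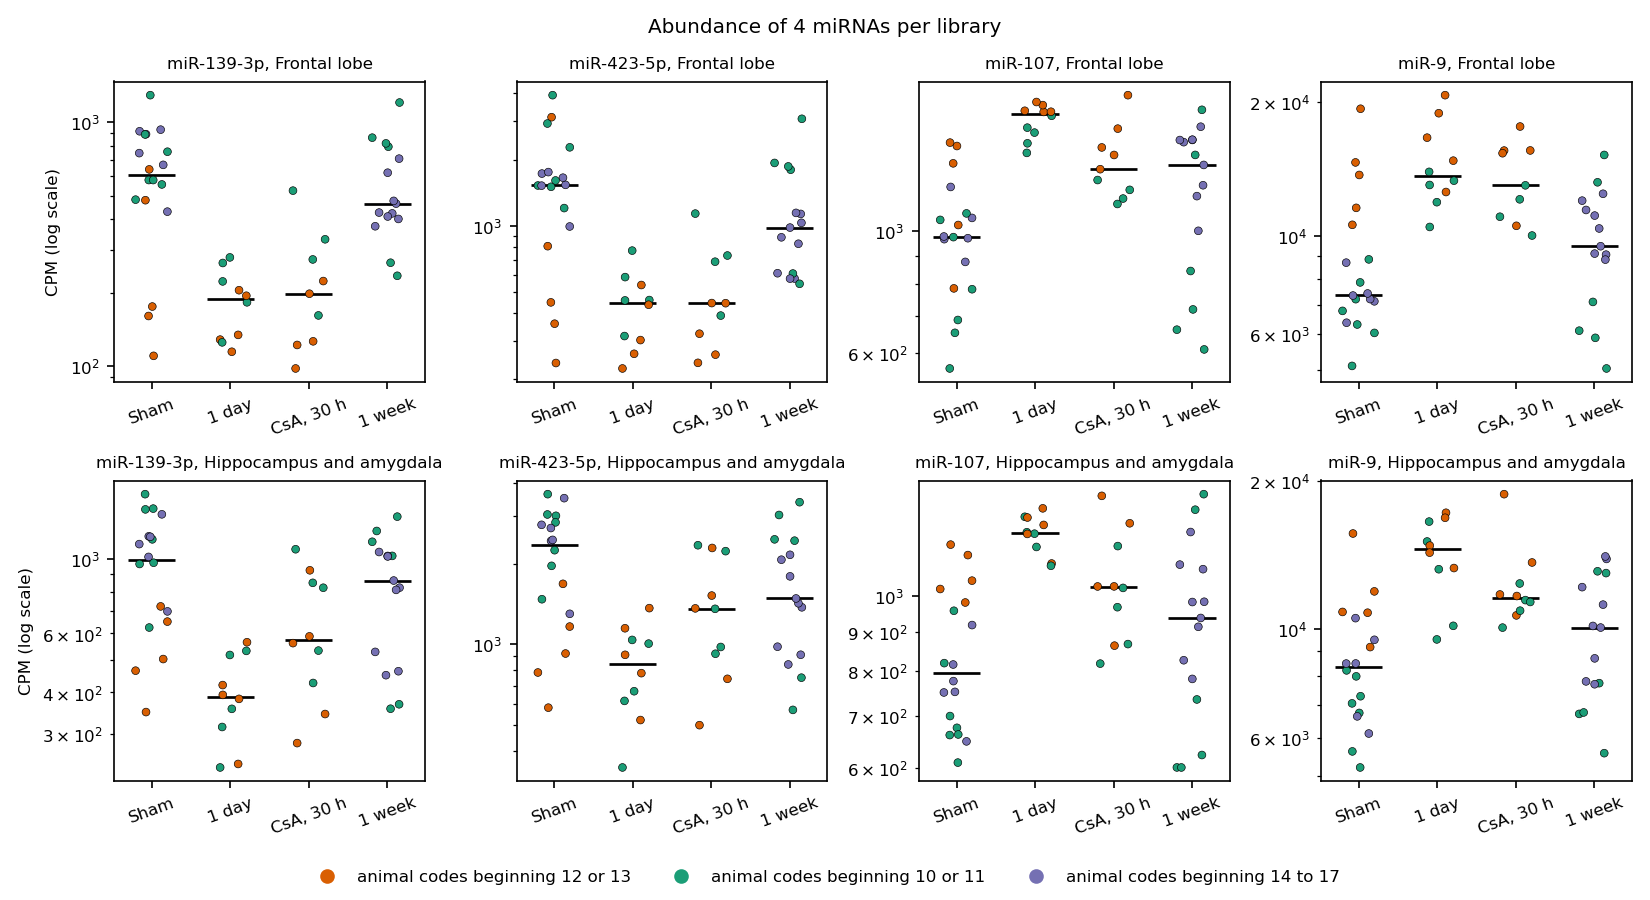
Abundance in CPM (log scale) of miR-139-3p, miR-423-5p, miR-107 and miR-9 per library by group, frontal lobe above and hippocampus and amygdala below; points are libraries coloured by the first 2 digits of the animal code and black lines are medians. Values are scaled over all libraries and so differ slightly from those in the text. miR-139-3p averages 185.2 CPM at 1 day and 626.1 in sham in the frontal lobe, and miR-9 14080 and 8675 in the hippocampus and amygdala.

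Both regions come from the same animals, and their 1 day minus sham log2 fold changes correlated across 280 miRNAs at r = 0.894. Shuffled groups of the same animals with no effect gave a median of 0.242 (-0.171 to 0.659), and disjoint parts of the animals gave 0.791. The covariance was 0.406 against 0.0158 with no effect. Of the calls in this set, 48 were higher in both regions and 52 lower in both, where independent lists would share 15.3 and 15.3. Codes and library totals were spread unevenly between 1 day and sham animals in both regions. Shuffled groups and independent lists do not keep that unevenness, so the likeness of the regions cannot tell injury from it. The interaction found 0 of 298 miRNAs by edgeR whose 1 day effect differed between regions (9 at an unadjusted p under 0.05, 0 with DESeq2, 0 with limma voom). The smallest adjusted p was 0.856, for miR-708-5p (log2 0.27) and others.

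One week after injury, few miRNAs stood apart from sham. In the frontal lobe (15 against 18 animals) miR-9 was at 9375 ± 2540 CPM against 9129 ± 4105 (log2 0.04), miR-139-3p at 550.9 ± 266.3 against 623.4 ± 294.3, and miR-21-5p at 134.5 ± 21.3 against 112.0 ± 36.1 (log2 0.27, adjusted p = 0.683). In the hippocampus and amygdala the low-abundance miR-190a fell from 2.69 ± 1.83 to 1.18 ± 0.891 CPM (log2 -1.22, SE 0.30, adjusted p = 0.0467), the only call there, lost without any of 18 of the 33 animals (adjusted p up to 0.117); it was named because the count was so small, after its values were seen.

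edgeR called 0 of 284 in the frontal lobe, with 19 at an unadjusted p under 0.05 where 14.2 would be expected by chance; DESeq2 called 1 and limma voom 53, and edgeR 23 without shallow libraries and 19 after thinning to equal totals. The smallest p values belonged to miR-574-5p (log2 -1.77, adjusted p = 0.364), miR-10386 (-2.35, 0.364), miR-676-3p (-0.18, 0.561), miR-187 (0.27, 0.561) and miR-4331-3p (-1.95, 0.561), which did not pass. Without sham replicate 15 miR-574-5p was at 0.07 and miR-4331-3p at -0.67, and without sham replicate 16 miR-10386 was at -1.72, so the direction of the first and the size of all 3 rested on single sham animals. The hippocampus and amygdala had 1 call of 290 (0 higher, 1 lower), with 15 at an unadjusted p under 0.05; DESeq2 called 3 and limma voom 0. miR-4331-3p (-1.52, adjusted p = 0.0695), miR-10386 (-2.11, 0.0890), miR-574-5p (-0.79, 0.695) and miR-205 (-1.22, 0.695; -0.59 without sham replicate 15) followed without passing. With single animals left out the count ran from 0 to 3. miR-190a was the call lost in 18 of 33 such cases (adjusted p up to 0.117), miR-4331-3p passed without any of 8 (from 0.0337) and miR-10386 without 1 week replicate 3, 14 or 15 (from 0.0337). The miR-190a call was lost with limma voom (adjusted p = 0.0641), with no low-count filter (0.0939) and without shallow libraries (0.133). No member of any list passed over all miRNAs in either region, and no list was called by camera. By fry the endothelial and vascular smooth muscle list was higher in the frontal lobe (adjusted p = 0.0299, median log2 0.10, 0 of 11 members called; camera adjusted p = 0.0821). Over the list alone 1 epithelial and 1 caudal HOX-cluster miRNA were lower in the hippocampus and amygdala. Restricting both groups to animals with the letter U (6 sham, 9 at 1 week) gave 49 calls in the frontal lobe (20 higher, 29 lower) and 12 in the hippocampus and amygdala, while codes beginning 11 gave 0 by edgeR in both (19 and 41 at an unadjusted p under 0.05). Log2 fold changes at 1 day and at 1 week correlated at r = 0.295 in the frontal lobe and 0.649 in the hippocampus and amygdala. With no effect the shared sham libraries alone gave medians of 0.44 (-0.271 to 0.825) and 0.408 (-0.00357 to 0.714). Divided sham groups gave 0.133 and 0.426. Covariances were 0.0796 and 0.102 against 0.0311 and 0.0201 with no effect. The 1 week effect differed between regions for 0 of 298 miRNAs by edgeR (8 at an unadjusted p under 0.05, 0 with DESeq2, 0 with limma voom).

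The later time was also set directly against the earlier one, with no animal code group (letter and first digits) in common. miR-139-3p was 3.15-fold higher at 1 week in the frontal lobe (550.9 ± 266.3, n = 15, against 174.9 ± 55.7 CPM, n = 10; log2 1.66, SE 0.30, adjusted p = 0.000182) and 2.05-fold higher in the hippocampus and amygdala (adjusted p = 0.00266). miR-423-5p was 2.79-fold and 2.00-fold higher. miR-9 was lower at 1 week by 1.47-fold in both regions (adjusted p = 0.0114 and 0.00529), as were miR-15b (1.56-fold and 1.55-fold) and miR-107 (log2 -0.38 and -0.41). Neuronal miR-124a (log2 0.38, adjusted p = 0.00623) and miR-219b-3p (0.20, adjusted p = 0.0488) were higher at 1 week in the frontal lobe, and miR-155-5p (-0.24, adjusted p = 0.0277) and miR-451 (-1.65, adjusted p = 0.0124) were lower in the hippocampus and amygdala. With 1 animal left out, miR-219b-3p did not pass in 15 of 25 cases (adjusted p up to 0.112), miR-155-5p in 8 (up to 0.125) and miR-451 without 1 day replicate 9 (0.0593). let-7e was 1.62-fold and 1.61-fold higher.

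Counts were 102 of 284 in the frontal lobe (66 higher, 36 lower; RLE 56 and 56, DESeq2 57 and 63, without let-7 51 and 55) and 85 of 290 in the hippocampus and amygdala (34 and 51; RLE 39 and 37, DESeq2 52 and 45, without let-7 38 and 33). Other large frontal increases were miR-4332 (11.6-fold), miR-10386 (9.07-fold), miR-193a-5p (3.80-fold), miR-885-3p (3.63-fold), miR-769-3p (2.97-fold), miR-1307 (2.94-fold), miR-296-3p (2.67-fold), miR-7134-3p (2.09-fold), miR-874 (2.07-fold) and miR-370 (2.05-fold). The decreases of miR-148b-3p (1.83-fold), miR-135 (1.71-fold), miR-199b-5p (1.62-fold), miR-27a (1.59-fold) and miR-204 (log2 -0.59) were smaller, and that of miR-135 was lost without 1 day replicate 8 or 9 (adjusted p up to 0.0879). There were also increases in the hippocampus and amygdala, where miR-10386 (6.32-fold), miR-4332 (6.56-fold), miR-193a-5p (2.79-fold), miR-92b-5p (2.72-fold) and miR-2366 (1.75-fold) were higher and miR-363 (1.78-fold), miR-17-3p (1.61-fold), miR-374a-5p (1.57-fold), miR-450c-3p (1.56-fold), miR-31 (1.46-fold) and miR-181a (1.46-fold) lower. Of these calls, miR-363 was lost without 1 day replicate 3 or 10 (up to 0.0629), miR-181a without 1 day replicate 10 (0.0653) and miR-31 without any of 18 of 25 animals (up to 0.139). miRNAs reported in traumatic brain injury had 2 higher and 5 lower of 22 in the frontal lobe (same over the list alone) and 0 and 11 of 23 in the hippocampus and amygdala (2 and 14 adjusted over the list alone), with camera at adjusted p = 0.0821 for both and fry at 0.0354 and 0.00143, lower. p53 and cell death miRNAs had 0 higher and 4 lower of 9 in each region (4 and 5 lower over the list alone; fry adjusted p = 0.0107 and 0.0359), and erythrocyte miRNAs were lower by fry in the hippocampus and amygdala (0.00282). Without shallow libraries the counts were 39 and 40, and after thinning the remaining libraries to equal totals 32 and 28. With codes beginning 11 alone (4 animals at 1 week against 5) they were 0 and 0 by edgeR, with 70 and 47 at an unadjusted p under 0.05. The comparison shares its 1 day libraries with 1 day minus sham, so that opposite values arise without any effect. The log2 fold changes of both correlated at r = -0.875 in the frontal lobe and -0.926 in the hippocampus and amygdala. No effect gave -0.631 (-0.907 to -0.00885) and -0.632 (-0.843 to -0.268), and divided 1 day groups -0.832 and -0.814. The covariances were -0.466 and -0.292 against -0.0555 and -0.0368 with no effect. Of the calls, 58 were higher at 1 week and lower at 1 day than sham in the frontal lobe and 28 the reverse (17.2 and 6.7 for independent lists), with 32 and 48 in the hippocampus and amygdala (6.9 and 14.4).

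Cyclosporine A was compared with untreated injury at 1 day, the nearest untreated time (30 hours against 1 day). In the frontal lobe (9 against 10 animals) abundances were close: miR-9 at 13550 ± 2854 against 13810 ± 2975 CPM (log2 -0.03), miR-139-3p at 228.4 ± 128.4 against 174.9 ± 55.7, and miR-21-5p at 140.4 ± 41.4 against 139.1 ± 27.2 (log2 0.01). In the hippocampus and amygdala (10 against 10) the smallest p values included those of miR-125a, 2600 ± 383.4 against 2098 ± 301.4 CPM (log2 0.31, SE 0.09, adjusted p = 0.107), and of the endothelial miR-126-5p, 407.2 ± 56.5 against 556.3 ± 140.7 CPM (log2 -0.45, SE 0.13, adjusted p = 0.107). Neither passed with all animals, though miR-125a did without 1 day replicate 6, CsA replicate 1 or CsA replicate 2 (adjusted p = 0.0214, 0.0173 and 0.0495), and miR-126-5p without either of the first 2 (0.0288 and 0.0393). miR-21-5p was at 106.7 ± 17.0 CPM with CsA and 140.7 ± 35.9 without (log2 -0.40, adjusted p = 0.128).

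edgeR called 0 of 284 in the frontal lobe (12 at an unadjusted p under 0.05, 14.2 expected by chance; 0 with DESeq2, 0 with limma voom), where the smallest adjusted p was 0.931, for muscle-enriched miR-1 (log2 0.54), miR-335 (0.47), miR-153 (0.44), miR-296-5p (0.61) and miR-339 (0.31). It called 0 of 290 in the hippocampus and amygdala, where 69 had an unadjusted p under 0.05 against 14.5 expected; DESeq2 called 13 and limma voom 33. Without single animals edgeR called 9 (1 day replicate 6), 13 (CsA replicate 1) or 5 (CsA replicate 2). miR-1343 (log2 0.66, adjusted p = 0.107), miR-193a-5p (0.95, 0.115) and miR-328 (0.48, 0.115) were also among the 5 smallest p, and each passed in all 3 of these cases (adjusted p from 0.00614 to 0.0495). Over each list alone, 1 skeletal muscle miRNA was higher in the frontal lobe. For the hippocampus and amygdala, 2 endothelial, 1 let-7 and 1 p53 and cell death miRNA were lower and erythrocyte miRNAs gave 1 higher and 1 lower. CsA minus 1 day and 1 day minus sham, which share the 1 day libraries, correlated at r = -0.734 in the hippocampus and amygdala (no effect: -0.574, from -0.806 to -0.17; divided 1 day groups: -0.569) and at -0.152 in the frontal lobe (no effect: -0.577, from -0.89 to 0.0588; divided groups: -0.0191). The covariances were -0.147 and -0.0324 against -0.036 and -0.0591 with no effect.

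Against sham, CsA-treated animals shared many differences with untreated animals at 1 day. miR-451 was 4.61-fold higher in the frontal lobe (7.36 ± 9.29 CPM, n = 9, against 1.38 ± 2.34, n = 18; log2 2.21, SE 0.53, adjusted p = 0.00221; medians 1.39 and 0.565 CPM scaled over all libraries) and 3.09-fold higher in the hippocampus and amygdala (n = 10 and 18, adjusted p = 0.0211). Single animals weighed on both values. The frontal fold was 3.07 without CsA replicate 2 (adjusted p = 0.0147) and 6.56 without sham replicate 7, and the other call was lost without CsA replicate 7 (0.0563). miR-9 rose 1.48-fold (adjusted p = 0.00944) and 1.40-fold (adjusted p = 0.0146), and miR-212 1.56-fold and 1.79-fold, the frontal call of the latter being lost without sham replicate 3 or CsA replicate 1, 4, 5 or 8 (adjusted p up to 0.0766). From the oligodendrocyte and myelin list, miR-219b-3p fell in both regions (log2 -0.35, adjusted p = 0.00176, and -0.34, adjusted p = 0.0256, the latter up to 0.0584 without CsA replicate 3 or 6), and miR-338 fell in the hippocampus and amygdala (-0.44, adjusted p = 0.0149). miR-139-3p was 2.72-fold lower in the frontal lobe (adjusted p = 0.00128) and 1.52-fold lower in the hippocampus and amygdala (adjusted p = 0.0483, up to 0.137 and lost without any of 20 of the 28 animals). In the latter, miR-935 rose 1.66-fold (80.2 ± 15.0 against 47.9 ± 10.3 CPM, adjusted p = 1.92e-05) and miR-18a fell from 39.1 ± 12.2 to 21.9 ± 2.77 CPM (adjusted p = 0.000580).

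The frontal lobe had 97 calls of 284 (42 higher, 55 lower; RLE 53 and 48, DESeq2 57 and 49; limma voom 153 calls, letter U alone 155), and the hippocampus and amygdala 59 of 290 (32 and 27; RLE 25 and 32, DESeq2 28 and 36, without let-7 22 and 29; 35 calls without CsA replicate 2). Frontal increases named by rule included miR-374a-5p (1.70-fold), miR-137 (1.62-fold), miR-17-3p (1.58-fold), miR-142-5p (1.58-fold; adjusted p = 0.103 without CsA replicate 5) and miR-505 (1.58-fold; 0.0558 without CsA replicate 4), while miR-142-3p was at log2 -0.04 there and at -0.46 in the hippocampus and amygdala and did not pass. Decreases included miR-10386 (24.4-fold, or 15.8-fold without sham replicate 16). Without sham replicate 15 miR-4332 went from 8.39-fold to 4.36-fold, miR-4331-3p from 7.98-fold to 3.30-fold and miR-574-5p from 5.92-fold to 1.67-fold, which did not pass (adjusted p = 0.0708). Others lower were miR-423-5p (3.11-fold), miR-885-3p (3.02-fold) and miR-671-5p (2.23-fold). The hippocampus and amygdala showed miR-505 (1.74-fold), miR-326 (1.70-fold), miR-221-5p (1.65-fold), let-7d-3p (1.56-fold), miR-99a-3p (1.55-fold) and miR-129a-3p (1.55-fold) higher. Lower there were miR-10386 (14.7-fold), miR-4332 (4.07-fold; adjusted p = 0.0502 without sham replicate 6 and 0.0532 without CsA replicate 2), miR-769-3p (1.99-fold), hepatic miR-122-5p (1.65-fold) and miR-1285 (1.53-fold). The calls of miR-129a-3p and miR-1285 were each lost without any of 19 of the 28 animals (adjusted p up to 0.183 and 0.0967). Signs turned for miR-4332 and miR-1285 with log10 total as a covariate and with codes beginning 12 or 13, and for miR-129a-3p with codes beginning 11. miR-124a fell in the frontal lobe (log2 -0.42) and was at -0.14 in the hippocampus and amygdala, which did not pass. miR-21-5p (0.34 and 0.03), miR-155-5p (0.06 and 0.03) and miR-132 (-0.08 and -0.09) did not pass in either, though frontal miR-21-5p passed without any of 8 of 27 animals (adjusted p from 0.0216). Of miRNAs reported in traumatic brain injury, 6 of 22 rose and 2 fell in the frontal lobe, and 7 of 23 rose and 0 fell in the hippocampus and amygdala (6 and 2, and 8 and 0, over the list alone; fry adjusted p = 0.00495 and 0.0252, camera 0.150 and 0.175). Fry further placed frontal p53 and cell death miRNAs higher (adjusted p = 0.0306) and, in the hippocampus and amygdala, DLK1-DIO3 cluster (0.0373) and erythrocyte miRNAs (0.0359) higher and oligodendrocyte and myelin miRNAs lower (0.0359). Codes beginning 11 to 13 left 37 and 6 calls. With codes beginning 12 or 13 both regions gave 0 calls by edgeR (40 and 34 at an unadjusted p under 0.05). With codes beginning 11 edgeR gave 0 (71 at an unadjusted p under 0.05) and 25. With log10 total as a covariate 20 and 2 were left. Fold changes of both injured groups against the shared sham animals correlated at r = 0.925 and 0.875 (no effect 0.38, from -0.29 to 0.8, and 0.367, from -0.0678 to 0.696; divided sham groups 0.821 and 0.709). The covariances were 0.514 and 0.246 against 0.0312 and 0.02. For the frontal lobe 32 calls were higher and 52 lower in both groups (7.8 and 14.3 for independent lists), and in the hippocampus and amygdala 30 and 22 (9.0 and 5.5). Across regions the CsA minus sham fold changes correlated at r = 0.544, within the range with no effect (0.245, from -0.192 to 0.635), and at 0.423 with divided animals. Their covariance was 0.167 against 0.0178 with no effect. With divided animals it was 0.144, outside the range with no effect (-0.0346 to 0.0631). Of the calls, 13 were higher and 20 lower in both regions (4.7 and 5.3 for independent lists). The uneven codes and totals enter every comparison with sham here, so the shared calls cannot tell injury from them. For 0 of 298 miRNAs did the effect differ between regions by edgeR (73 at an unadjusted p under 0.05; DESeq2 29, limma voom 6, 18 with log10 total as a covariate), the smallest adjusted p being 0.0694, shared by miR-7134-3p (log2 0.87), miR-9788-3p (0.84), miR-664-5p (0.45), miR-150 (0.41) and miR-126-5p (-0.55). That count was 10, 35 and 14 without the animal of frontal CsA replicate 2, 8 or 9, and 16, 25, 2 and 15 without that of frontal sham replicate 1, 9, 12 or 18.

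The regions themselves differed within the 18 sham animals. miR-7-5p, a miRNA of neuroendocrine and forebrain neurons, was higher in the hippocampus and amygdala (15310 ± 3584 against 7797 ± 1947 CPM, log2 0.97, SE 0.09, adjusted p = 1.65e-12), in 18 of 18 animals. miR-204, abundant in the choroid plexus, was 2.77-fold higher (364.5 ± 333.5 against 97.8 ± 40.4 CPM, adjusted p = 3.25e-05, 18 of 18), and miR-31 was higher by log2 0.97 (18 of 18). miR-219b-3p and miR-338, both on the oligodendrocyte and myelin list, were lower there by log2 -0.97 and -0.78 (228.5 ± 44.7 against 442.2 ± 56.1 CPM, adjusted p = 6.14e-18, for the former), each in 18 of 18 animals. miR-146b was 5.24-fold lower (5.78 ± 3.33 against 26.6 ± 9.68 CPM, 17 of 18). miR-132 fell by 0.73 on the log2 scale (17 of 18).

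Of 298 miRNAs, 141 differed, 65 higher and 76 lower in the hippocampus and amygdala. Others named were miR-92b-3p (1.94-fold), miR-105-1 (log2 0.92), miR-92b-5p (1.89-fold), miR-532-3p (1.78-fold), miR-184 (1.76-fold), miR-139-3p (1.62-fold), miR-489 (1.61-fold), miR-296-3p (1.57-fold) and miR-1343 (1.55-fold), all higher. miR-23b (1.87-fold), miR-27b-3p (1.82-fold) and miR-1 (1.93-fold) were lower. miR-96-5p, miR-141, miR-200b, miR-429, miR-183 and miR-182 were 62.0-, 53.2-, 26.9-, 24.2-, 19.0- and 10.0-fold lower, with wide spread between frontal libraries (miR-200b 39.2 ± 65.0 against 1.42 ± 2.72 CPM). Leaving out the animal of frontal sham replicate 18 or 5 moved miR-96-5p to 37.0-fold or 155-fold, miR-141 to 35.0-fold or 115-fold and miR-200b to 17.1-fold or 49.7-fold. Without replicate 1 miR-96-5p was at 40.9-fold and miR-200b at 17.3-fold, and without replicate 2 miR-96-5p was at 95.8-fold. All remained past the threshold. miR-155-5p (log2 -0.52), miR-126-3p (-0.42), miR-212 (-0.43) and miR-124a (-0.28) were lower too, and miR-9 (-0.07) and miR-21-5p (-0.12) did not pass. Astrocyte-associated miRNAs had 7 of 9 lower and 0 higher, also over the list alone, the only list called by camera in any comparison (adjusted p = 0.0157; adjusted p = 0.944 with an estimated correlation; fry adjusted p = 1.15e-06). Besides miR-23b and miR-27b-3p, miR-24-3p (log2 -0.50) was lower, while miR-29a-3p (-0.06) did not pass. Of the others, the miR-17-92 group had 0 higher and 7 lower of 11 (miR-18a, log2 -0.56; miR-20a-5p, -0.42), the let-7 family 1 and 7 of 10 (let-7g -0.41, let-7e 0.21), p53 and cell death miRNAs 0 and 6 of 9 (miR-16, -0.46), the miR-181 family 0 and 2 of 5 (miR-181a, -0.55), oligodendrocyte and myelin miRNAs 0 and 2 of 4, and the DLK1-DIO3 cluster 5 and 0 of 19 (miR-127, 0.18), each the same over the list alone. The calls of let-7e and miR-127 were each lost without the animal of frontal sham replicate 4, 9, 10 or 12 (adjusted p up to 0.110 and 0.143). Neuron-enriched miRNAs gave 2 and 5 of 11 (3 and 5 over the list alone), with miR-137 higher (log2 0.46). Fry also gave lower values for oligodendrocyte and myelin (adjusted p = 2.82e-11), let-7 and miR-17-92 (0.000605 each), p53 and cell death (0.00152), miR-181 (0.00191), traumatic brain injury (0.00203), endothelial and vascular smooth muscle (0.00282) and neuron-enriched miRNAs (0.0359), and higher ones for the DLK1-DIO3 cluster (0.00680).

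**Figure D3:**
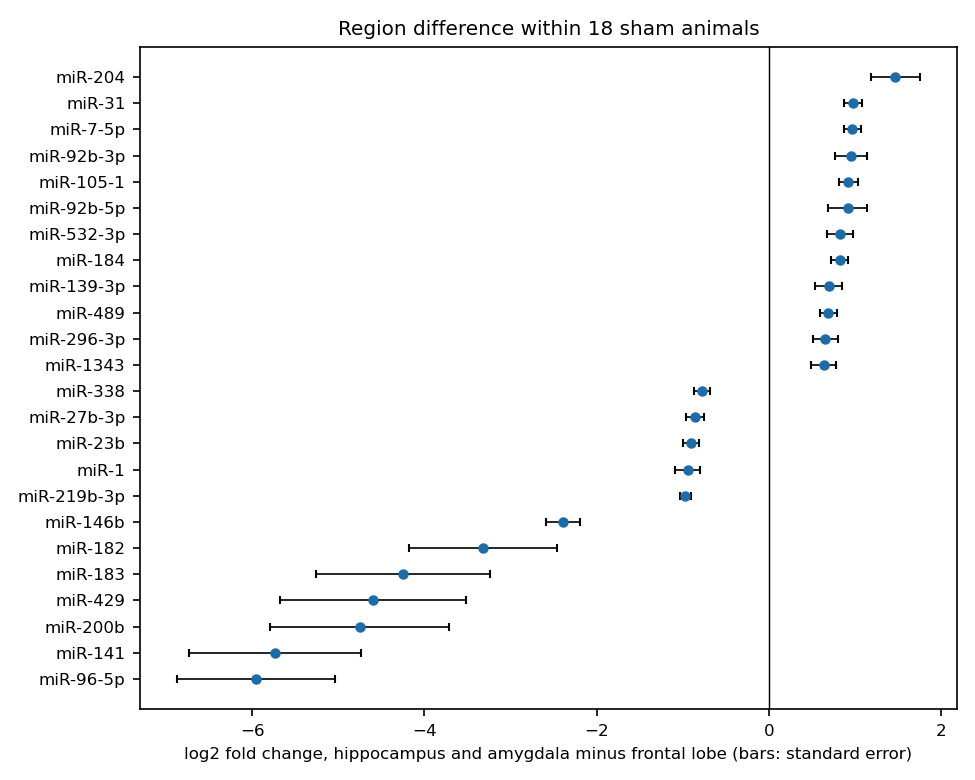
log2 fold change of the named miRNAs, hippocampus and amygdala minus frontal lobe, in 18 sham animals, with the animal as a block; points are edgeR estimates, bars the standard error and the vertical line no difference. miR-204 (1.47) lies at the top and miR-96-5p (-5.95) at the bottom, where the standard errors are widest.

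**Figure D4:**
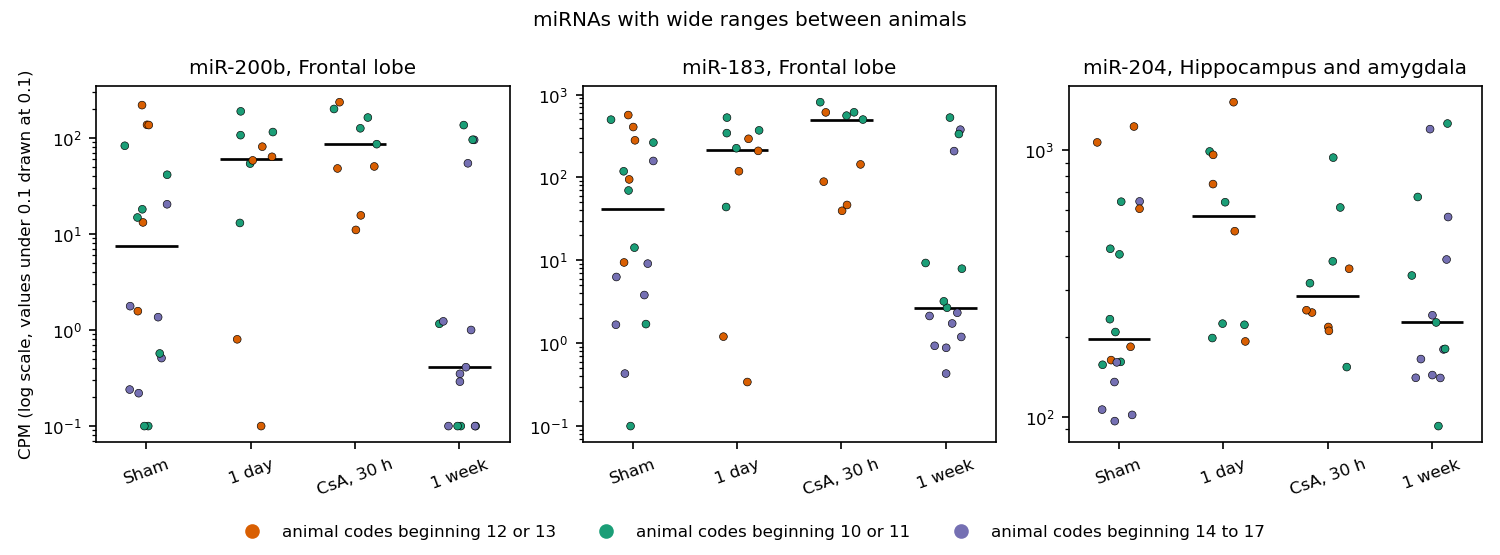
Abundance in CPM (log scale, values under 0.1 drawn at 0.1) of miR-200b and miR-183 in the frontal lobe and of miR-204 in the hippocampus and amygdala, per library by group; points are libraries coloured by the first 2 digits of the animal code and black lines are medians. miR-200b reaches 234.8 CPM in the frontal lobe with a sham median of 7.47, and miR-204 runs from 96.5 to 1229 in sham.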

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

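Planned before the data were examined were the comparisons of the groups with edgeR, DESeq2 and limma voom, and written down before their results were seen were the tests of chance assignment to the injured groups and of miR-205. Tests of thinning, let-7, log10 total, sham slopes, animal codes, shared libraries, totals and single animals, that of injury for the third pattern and the other splits were chosen after the result was seen.

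In the 1 day and CsA groups, single animals stood apart from their group in 4 of 92 tests of gap against range, where chance gives about 4.6. The sham and 1 week groups, with more than 10 animals each, were not tested in this way, so their extreme libraries do not enter this count. At 1 day in the frontal lobe, replicate 1 had log2 CPM 7.76 for miR-132 (nearest 7.55, median 7.48, n = 10) and replicate 2 had 5.58 for miR-142-5p (nearest 4.98, median 4.62). In the hippocampus and amygdala of CsA-treated animals, replicate 3 had 6.15 for miR-21-5p (nearest 6.54, median 6.77, n = 10) and replicate 1 had 14.2 for miR-9 (nearest 13.7, median 13.5). The 1 week and 1 day groups differed, tested directly, for 102 miRNAs in the frontal lobe and 85 in the hippocampus and amygdala, but no 1 week animal shared both code letter and first digits with a 1 day animal, so that time after injury could not be told apart from the code (codes 11 alone gave 0 and 0 by edgeR, with 70 and 47 at an unadjusted p under 0.05, and thinning 32 and 28).

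The first pattern is the large difference between 1 day and sham, with 127 and 141 calls (frontal, then hippocampus and amygdala). Leaving out the shallow libraries and thinning the others to equal totals left 112 and 118 calls. Leaving out let-7 gave 135 and 131, and log10 total as a covariate 56 and 57. These counts argue against a few abundant miRNAs or the total as the whole cause. They argue against counting depth as the whole cause only among libraries that were not shallow. A library property that goes with the total may contribute, since slopes on log10 total among sham animals alone correlated across miRNAs with the 1 day differences at 0.698 and 0.585 (upper ends of shuffled values 0.67 and 0.573). Without the 2 sham libraries with the lowest totals the correlations were 0.802 and 0.713. The sham libraries also enter the 1 day differences. Slopes among the 1 week libraries, which do not, correlated with them at 0.795 and 0.86 (upper ends of shuffled values 0.763 and 0.757). The animal code may contribute as well, or instead. Codes beginning 12 or 13 gave 0 calls with 5 against 5, a count reached in 0 and 0 of 100 draws of 5 other sham animals (medians 129 and 101). Of the called miRNAs, 122 of 125 and 128 of 140 kept their sign there, at a median of 0.606 and 0.432 of the full difference. They were chosen for being called in a comparison that includes these libraries. The 5 sham animals with these codes differed from the other sham animals in 74 and 79 miRNAs and in the direction of the 1 day group (mean correlation 0.775 and 0.742, random upper ends 0.665 and 0.536). With these codes, 1 day totals were 1.20 and 1.21 times those of sham, against 2.44 and 2.09 times with all animals. Each draw thus changed code and library total together and cannot tell the code from a property that goes with the total. Injury stays open beside both: codes 11 gave 91 and 112 calls (55 without frontal 1 day replicate 2) with totals 3.41-fold and 2.95-fold apart, and only animals with the letter U 163 and 136, but sham animals with this letter had codes beginning 14 or 16, so that no sham animal shared both letter and first digits with a 1 day animal and injury could not be told apart from the code as a whole.

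The second pattern is that CsA minus 1 day ran opposite to 1 day minus sham in the hippocampus and amygdala (r = -0.734), although 0 miRNAs passed there by edgeR (69 at an unadjusted p under 0.05, DESeq2 13, limma voom 33, and 13 by edgeR without CsA replicate 1). Shared 1 day libraries alone are argued against by the covariance with these libraries divided, -0.123, outside the range with no effect (-0.0449 to 0.0289). A difference in mean totals is argued against by a ratio of 1.01 between the groups. Equal totals cannot exclude a difference in a library property that went with the total among sham animals. Chance assignment is argued against by the splits, of which 1 of 100, the real one, had as many unadjusted p under 0.05 (highest other 64). A partial return toward sham levels with CsA in this region may be stated only as a hypothesis, found and tested on the same data. The 6 hours between the groups' survival times remain open beside it, as do such a library property and the animal code. In each group 5 of 10 animals had codes 12 or 13, but the CsA group had more with 12 and fewer with 13. The infusion could not be told apart from CsA, since no injured group was labelled as infused without it.

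The third pattern is the wide spread of miR-200b, miR-141, miR-429, miR-182, miR-183 and miR-96-5p between frontal libraries: all 6 were over 10 CPM in 22 of 52 libraries and none in 17, against 0 and 46 of 53 in the hippocampus and amygdala. Squamous epithelium in the tissue could not be decided, as miR-205 reached 0.0201 of miR-200b over the frontal libraries. Injury could not be decided either, with 0 of the 6 called in 1 day minus sham and medians of miR-200b at 7.47 CPM in sham, 60.8 at 1 day, 85.9 with CsA and 0.413 at 1 week. Another epithelium or a neighbouring structure taken with some frontal blocks was not tested.

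Other splits of the animals gave as many calls as the real one in 1 of 100, the real split itself, for 1 day minus sham (127 against a highest other of 42 in the frontal lobe, 141 against 70 in the hippocampus and amygdala) and for CsA minus sham (97 against 78, and 59 against 3). The same held for 1 week minus 1 day in the frontal lobe (102 against 48) and, at 1 of 40, for the region difference (141 against 63). Such counts were thus rare among random splits in these 6, though the shares were not adjusted over the comparisons. For 1 week minus 1 day in the hippocampus and amygdala 2 of 100 splits reached the real count (85, highest other 87), so a random split can reach it, though rarely. For 1 week minus sham in the hippocampus and amygdala 6 of 100 splits reached the real count (1, highest other 45), so chance was not excluded. Where the real count was 0 every split reaches it, so that 100 of 100 for frontal 1 week minus sham (highest other 9) and for CsA minus 1 day in each region (highest other 1 and 9), and 40 of 40 for the 3 interactions (highest other 1, 1 and 63 for 1 day, 1 week and CsA), say nothing about chance. By the number with an unadjusted p under 0.05 instead, such a count was rare for CsA minus 1 day in the hippocampus and amygdala (69, by 1 of 100, highest other 64). Chance was not excluded for frontal 1 week minus sham (19, reached by 50 of 100 splits, highest other 84) or frontal CsA minus 1 day (12, by 18 of 100, highest other 58). Nor was it for the interactions (9, 8 and 73, by 24, 30 and 3 of 40, highest other 41, 53 and 118). Splits that called 45 or 63 miRNAs where the real count was 1 or 0 may reflect a structure among the animals beyond their groups, which was not tested. Where the real count was high, as with 87 against 85, splits close to the real one may also give many calls.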

How the results depend on the processing

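Of 194 checks of a main count or total, 142 stayed within 1.5 times the main value or on the same side of the threshold and 52 did not; for named miRNAs, of 7014 checks 6170 were unchanged in call and direction, 666 lost the call, 169 gained it and 9 turned sign. Alternatives chosen after seeing the data were the entries as deposited, log10 total as a covariate, no let-7 family, thinning, codes beginning 12 or 13 or beginning 11, and single libraries left out in turn; the rest were planned, and all could be run. Regions are given as frontal, then hippocampus and amygdala. Where fewer animals entered (codes, letter, shallow libraries), lost calls partly follow from that; otherwise the cause was not tested. For 1 day minus sham (127, 141), log10 total left 56 and 57 calls, and codes 12 or 13 gave 0 and 0 by edgeR (61 and 53 at an unadjusted p under 0.05). For 1 week minus sham (0, 1), frontal counts were 1 with DESeq2, 53 with limma voom, 23 without shallow libraries, 7 with the code letter and 1 with the code prefix as covariate, 49 with letter U and 19 after thinning. The hippocampus and amygdala had 3 with DESeq2, 10 with the letter and 2 with the prefix as covariate, and 12 with letter U. It had 0 by edgeR with no filter, without shallow libraries, with only the 2 groups, with no code letter, with the entries as deposited, with log10 total, after thinning and with codes 11 (41 at an unadjusted p under 0.05), and 0 with limma voom. For CsA minus sham (97, 59), the frontal count was 153 with limma voom, 155 with letter U, 37 with codes 11 to 13, 20 with log10 total, and 0 by edgeR with codes 12 or 13 (40 unadjusted) or 11 (71 unadjusted). The other region had 6 with codes 11 to 13, 2 with log10 total, 25 with codes 11, and 0 by edgeR with codes 12 or 13 (34 unadjusted). Signs turned there for miR-4331-3p (log2 0.045), miR-574-5p (0.097), miR-4332 (0.33) and miR-1285 (0.039) with log10 total, for miR-4331-3p (0.123), miR-4332 (0.081) and miR-1285 (0.038) with codes 12 or 13, and for miR-129a-3p (-0.064) with codes 11. For 1 week minus 1 day (102, 85), counts without shallow libraries were 39 and 40, after thinning 32 and 28, and with codes 11 0 and 0 by edgeR (70 and 47 unadjusted), where miR-181a turned to 0.003 in the hippocampus and amygdala. CsA minus 1 day in the hippocampus and amygdala (0) gave 13 with DESeq2, 33 with limma voom, and 1 each without shallow libraries and with codes 11. The CsA interaction (0) gave 29 with DESeq2, 6 with limma voom and 18 with log10 total. The 1 list called by camera became 0 with an estimated correlation. Differences in log10 total against sham fell with codes 12 or 13 to 0.08 and 0.082 at 1 day and to 0.025 and 0.085 with CsA. The region difference (141) was 110 without the animal as a block, of which 107 were among the 141, so dropping the paired design changed the count by less than 1.5 times. With single libraries left out in turn, which the numbers at the start do not include, 334 of 372 counts stayed within 1.5 times the main one; of 13801 checks of named miRNAs 13355 were unchanged, 295 lost the call, 151 gained it and 0 called ones turned sign. The counts that moved ran from 0 to 3 for 1 week minus sham, from 0 to 13 for CsA minus 1 day and from 35 to 72 for CsA minus sham, all in the hippocampus and amygdala, and from 0 to 35 for the CsA interaction. Depth limited the 16 shallow libraries most, 9 frontal (5 sham, 4 at 1 week) and 7 of the hippocampus and amygdala (4 and 3), with 0 in the 1 day and CsA groups.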

Other observations

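All correlations with library totals in this part were chosen as tests after the result was seen.

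miR-34c, a miRNA of multiciliated cells and of p53 responses, varied widely between animals in the hippocampus and amygdala, from 4.38 to 799.9 CPM in sham (336.9 ± 285.9, n = 18), against 90.0 ± 51.3 in the frontal lobe. Its means in the hippocampus and amygdala were 359.1 ± 262.3 at 1 day and 371.7 ± 299.6 at 1 week. miR-204, abundant in the choroid plexus, was as uneven there (374.0 ± 339.9 in sham, from 96.5 to 1229, scaled over all libraries) and reached 619.0 ± 443.0 at 1 day, 369.1 ± 238.0 with CsA and 395.4 ± 376.9 at 1 week.

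miR-10386 followed the library total within the sham and 1 week groups. Pearson r with log10 total was -0.856 in the 18 sham animals of the hippocampus and amygdala (permutation p = 2e-05, the smallest possible, adjusted p = 4.9e-05 over 32 relations, -0.931 without the 2 farthest totals), with rho -0.938 (p = 2e-05, adjusted p = 0.00016). At 1 week r was -0.937 in the frontal lobe (rho -0.9) and -0.941 in the hippocampus and amygdala (rho -0.886), each n = 15 with adjusted permutation p of 4.9e-05 for r and 0.00016 for rho, and -0.903 and -0.94 without the 2 farthest. Of 32 further relations in the 1 day and CsA groups, none passed. At 1 day r was -0.704 in the frontal lobe (permutation p = 0.021, adjusted p = 0.069; rho -0.636, p = 0.054, adjusted p = 0.15; -0.425 without 2 animals) and -0.839 in the hippocampus and amygdala (p = 0.0039, adjusted p = 0.063; rho -0.624, p = 0.058, adjusted p = 0.15; -0.887). With CsA it was -0.784 in the frontal lobe (exact permutation p = 0.023, adjusted p = 0.069; rho -0.683, p = 0.05, adjusted p = 0.15; -0.263 without 2 animals) and -0.139 in the hippocampus and amygdala (permutation p = 0.7, adjusted p = 0.82; rho -0.127, p = 0.73, adjusted p = 0.87; -0.27). miR-107 correlated with the total in frontal sham animals at r = 0.646 (permutation p = 0.0041, adjusted p = 0.0053; rho 0.383, p = 0.12, adjusted p = 0.13), which rests on 2 animals, since r was 0.212 without them. In the sham hippocampus and amygdala r was 0.303 (p = 0.22, adjusted p = 0.23; rho 0.573, p = 0.015, adjusted p = 0.018) and 0.641 without the 2 farthest. At 1 week it was 0.792 in the frontal lobe (p = 0.0016, adjusted p = 0.0024; rho 0.514, p = 0.052, adjusted p = 0.06) and 0.82 in the hippocampus and amygdala (p = 0.00036, adjusted p = 0.00061; rho 0.707, p = 0.0043, adjusted p = 0.0066), with 0.646 and 0.712 without 2 animals, all by permutation. miR-139-3p and miR-423-5p had r of -0.241 (p = 0.34, adjusted p = 0.34; rho -0.498, p = 0.038, adjusted p = 0.045) and -0.44 (p = 0.034, adjusted p = 0.038; rho -0.635, p = 0.0057, adjusted p = 0.008) in the sham hippocampus and amygdala, and -0.506 and -0.553 without 2 animals. At 1 week r was -0.633 and -0.77 in the frontal lobe (adjusted permutation p = 0.014 and 0.0025; rho -0.643 and -0.65, 0.014 each) and -0.752 and -0.812 in the hippocampus and amygdala (0.0017 and 0.0006; rho -0.764 and -0.782, 0.0025 and 0.0017), with -0.516, -0.702, -0.708 and -0.765 without 2 animals.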
